A study of Mus musculus with 4 samples.

How the data were processed

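RNA methylated at the N6 position of adenosine (m6A) was captured from mouse embryonic stem cells with an antibody and sequenced. The labels give 4 samples: an m6A immunoprecipitate and a total mRNA input from wild-type cells, and the same pair from cells lacking both Gsk-3 kinases (double knockout, DKO). Each group had 1 library. Per the labels' protocols, feeder-free cells of the E14K line were kept for 14 days without leukaemia inhibitory factor (LIF), the cytokine that holds mouse embryonic stem cells in self-renewal. Polyadenylated RNA was selected with oligo(dT) beads, and m6A-bearing mRNA was then taken with antibody-coupled beads. Libraries were made from chemically fragmented RNA with an Ion Torrent barcoding kit.

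The data were 1 table of regions with their gene annotation. Bowtie2, DESeq and the mouse build mm9 are named, without version or role, in the submitters' processing notes. The peak caller and the rule by which regions entered the table are not given in the sources used here. Each region had a count for wild type and for the double knockout, and the file headers do not state whether it was normalized. The headers name the genotype and not the library type, and the counts were matched to the m6A libraries because only their titles carry the assay's name. A count from input, or one corrected for input, is not excluded. The deposited enrichment factor was a ratio, the wild-type count over the double-knockout count times a constant of 0.825. In the rows with a ratio the constant was the same to rounding (0.82478675 to 0.82478694). The ratio was blank wherever the double-knockout count was 0. The deposited read density was a signal, the wild-type count divided by the region's length in bases. The table had 0 input columns and held no library totals, and the sums over listed regions are not sequencing depth.

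Coordinates are printed as deposited. Of 6046 rows whose NCBI gene identifier was found in a RefSeq gene table of GRCm38.p6, 6035 (99.8%) lay within 5000 bases of that gene in GRCm38, and 1 region on chromosome Y ended at base 90789403. Coordinates are therefore described as matching GRCm38, although the submitters' processing notes name mm9. Of 3882 gene identifiers, 3772 matched the RefSeq table.

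The table's 7562 rows held 6697 distinct regions, each used once. Folds are wild type over double knockout after the authors' constant. For medians and ranks, log2 of double knockout over wild type was computed with a pseudocount of 0.5 on both counts. Where the double-knockout count was 0, the fold is a lower bound, set at a floor of 3 counts in that library. Counts have exact Poisson 95% intervals, ratios of 2 counts and shares have exact Clopper-Pearson intervals. The interval of a count of 0 reaches 3.69, so the bounds are less cautious than that interval. They also leave out the error of the wild-type count. Reads made by PCR without molecular identifiers are not independent molecules, so intervals and floors cover counting error only. With 1 library per group no p-value, standard error or number of significant regions was computed, and every comparison is between these libraries.

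For each gene, the region with the highest mean count of both libraries was used. A gene list's median was placed among the medians of 10000 random lists of the same size drawn from the same deciles of mean count. A low percentile means a larger fold than in matched genes, and the central 95% runs from 2.5 to 97.5. Lists with fewer than 5 listed members have no percentile. In simulated counts for 3882 genes, 1 ratio held for all genes but 200 made 4-fold lower. There, 89% of lists of 6 changed genes and 99% of lists of 10 lay outside the central 95%, against 2% and 4.5% of unchanged lists. The unchanged genes of this simulation varied by counting error only. Folds in the data also differed between genes, so the share found among real lists may be lower. Agreement between regions of a gene was measured as the share of variance lying between genes, after removing the mean of each count decile, against 1000 shuffles of regions within deciles. In simulated counts with 1 ratio for all regions this share was 34.6%, below the highest of the shuffles (40.4%).

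The gene lists, the rule for named genes and the first set of alternatives were fixed before the data were examined. The rule named Gsk3a, Gsk3b, Fto, Alkbh5, Mettl3, Mettl14 and Wtap wherever listed. It also named the 12 genes at each end of the change among regions at or above the median mean count, passing over predicted genes and pseudogenes, and the up to 4 members of each list with the largest absolute change. Some genes that the rule takes are not reported here. The plan ranked regions by input and used immunoprecipitate over input. Without input columns, mean count took the place of input, and the change in input, its relation to the m6A change and the genes named from it were left out. Because no listed region was higher in the double knockout, the 12 genes with the smallest folds are given in place of rises. Ribosomal S6 kinases were not counted as ribosomal proteins. Distance to the stop codon and the m6A sequence motif need a genome and were not analysed here. Alternatives covered scaling, pseudocount, count filter, regions per gene, threshold, annotation class and matching. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.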

Results

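The study compared m6A-modified mRNA in wild-type mouse embryonic stem cells and in cells lacking the kinases Gsk-3α and Gsk-3β, which restrain Wnt and insulin signalling. The table listed 6697 distinct regions under 3882 genes, with a count for each genotype from 1 library. Wild-type counts ran from 15 to 13799 (median 43) and double-knockout counts from 0 to 1100 (median 0). They summed to 573971 and 27072 over the listed regions. Regions were 150 to 5481 bases long, with a median of 191.

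The targeted genes could not be checked. Gsk3a was not listed, and Gsk3b appeared only through a region on chromosome 16 (38085117 to 38085347), annotated as upstream at a distance of -3769 bases from the transcription start, where wild type had 78 reads and the double knockout 3 (21.4-fold, 95% interval 7.07 to 106). That region lies outside the gene and checks nothing about the deletion. Of the m6A enzymes named in advance, the demethylase gene Fto had 4 regions. In its coding exon on chromosome 8 (91409479 to 91409633), 60 wild-type reads stood against 0, at least 16.5-fold lower in the double knockout. Its intronic regions had 29 and 17 against 0 and 15 against 2 (6.19-fold, 1.44 to 55.7), and the mean log2 value over all 4 was -4.86 against -6.64 for the exon. The other demethylase gene, Alkbh5, had 18 reads against 0 in a coding exon on chromosome 11 (60538469 to 60538625), at least 4.95-fold lower. Wtap, a subunit of the methyltransferase complex, had 63 against 0 in an intron on chromosome 17 (12981079 to 12981297), at least 17.3-fold lower. Mettl3 and Mettl14, the core of that complex, were not listed.

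The question of the main comparison was how m6A-modified mRNA differs between the genotypes. Counts as deposited were lower in the double knockout in every listed region, with 0 reads in the 1 region used for each of the 12 genes at the far end. At a count of 0 the value depends on the wild-type count alone, so the order of these 12 follows their read number. Tiam1, an activator of the GTPase Rac, had 807 wild-type reads against 0 in an intron on chromosome 16 (89863258 to 89863518), at least 222-fold lower, and 20 against 2 in a coding exon (89898218 to 89898370), so that its mean log2 value over both regions was -6.57 where the intronic region alone gave -10.38. At 3.09 wild-type reads per base, that intronic region was among the 67 densest, against a median of 0.219 over all regions. Tnc, the matrix glycoprotein tenascin C, had 570 against 0 in a coding exon (at least 157-fold), and Irs1, an adaptor of the insulin receptor, had 401 against 0 in its coding exon on chromosome 1 (82290455 to 82291353, at least 110-fold). The mean over the 5 regions of Irs1 was -6.37 on the log2 scale, against -9.37 for that region. The adhesion receptor Gpr133 (Adgrd1) had 394 against 0 and Arap2 388 against 0, both in introns. A region annotated to the lysine transfer RNA gene Trnak-cuu, at a distance of -48 bases from the transcription start, had 359 against 0. Which transcript gave those reads was not tested. Spatc1 had 337 in an intron, the protease gene Prss23 331, the chondroitin sulfotransferase gene Chst12 298, the embryonic myosin gene Myh3 296 and the cathepsin gene Ctsw 284, each against 0. From Trnak-cuu to Ctsw the bounds ran from 98.7-fold down to 78.1-fold. The mean over both regions of Chst12 was -6.39 on the log2 scale, against -8.94 for that region.

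At the other end stood Rn7sk, a small nuclear RNA that restrains transcription elongation, with 55 reads (41.4 to 71.6) against 12 (6.20 to 20.96), a 3.78-fold difference. The kinase gene Map3k10 had 39 against 8 (4.02-fold). Atf4, a transcription factor of the stress response, had 49 against 10 (4.04-fold, 2.02 to 8.95), and the cytoskeletal linker gene Dst 166 against 33 (4.15-fold, 2.84 to 6.23). The mean log2 value over the 5 regions of Dst was -3.12, against -2.04 for that region. Thrap3, Prmt6, Stc2, Spen, Fam129b, Pcdh1 and Pml had folds between 4.30 and 4.63, and the mean over the 3 regions of Fam129b was -2.93 against -2.13. The smallest fold of any listed region with double-knockout reads was 2.91, so these genes lie near the lower edge of the list.

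Over all 6697 regions, the median log2 of double knockout over wild type was -4.93, with quartiles of -5.79 and -3.55. The double-knockout count was 0 in 3382 regions (50.5%) and 1 to 3 in 1667. In the 3315 regions with double-knockout reads the fold ran from 2.91 to 622, with a median of 13.6. With zeros at their bound the median fold was 10.4, and 6689 regions were at least 4-fold and 3514 (52.5%) at least 10-fold lower. The lowest bound of a region without double-knockout reads was 4.12-fold, so all 3382 such regions pass 4-fold through the choice of floor. Listed regions with a double-knockout count at or above the wild-type count numbered 0, so the list holds 1 direction and that direction says nothing about regions outside it. A median-ratio factor computed from the 3315 regions with double-knockout reads centres those regions by construction: it moved every log2 value up by 3.77, which put 16 of the 79 named genes above 0 and carries no information on direction.

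**Figure D1:**
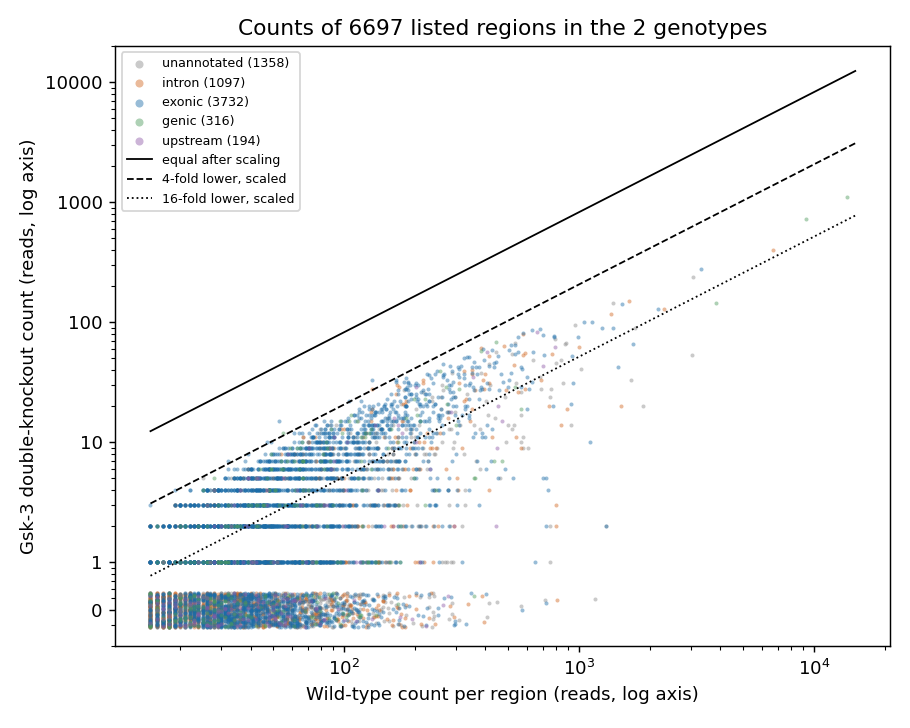
Each point is 1 of 6697 listed regions, with its wild-type read count on the x axis and its double-knockout read count on the y axis (log axes, double-knockout counts of 0 spread in a band at the bottom), coloured by annotation. Lines mark equal counts and 4-fold and 16-fold lower double-knockout counts after the authors' constant of 0.825. With zeros at their bound 6689 regions were at least 4-fold lower, a mark that every region without double-knockout reads passes through the floor.

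Among the lists fixed in advance, genes of early neural tissue had the lowest percentile among genes of like count at the pseudocount of 0.5, though at a pseudocount of 2 the mesoderm list was lower (0.67 against 4.54). Sox11, a neural transcription factor, had 1308 wild-type reads against 2 in a region spanning the end of its coding sequence and its 3'UTR on chromosome 12 (27340979 to 27342438), a 539-fold difference with a counting interval of 149 to 4459. Its other regions, in the 3'UTR, had 74, 63 and 22 reads against 0, and the mean over all 4 was -6.90 on the log2 scale against -8.75 for the deepest. Nes, the neural progenitor filament nestin, had 1110 against 10 in a coding exon on chromosome 3 (87977731 to 87979576), 91.6-fold (49.6 to 191). Notch1 had 56 against 0 and Sox3 55 against 0, at least 15.4-fold and 15.1-fold lower. The remaining members were Sox4 (175 against 4, 36.1-fold) and Tubb3 (37 against 2, 15.3-fold). The log2 value of Tubb3, -3.63, lay above the median of all genes (-4.85). The 6 listed of 34 neural genes had a median log2 of -6.48 (23.6-fold with zeros at their bound), at the 1.52 percentile of matched random lists. The place of this list outside the central 95% was lost at other pseudocounts (7.07 at 0.25 and 4.54 at 2) and on leaving out any 1 of its 6 genes, with percentiles from 2.71 to 6.78, whereas it was at 0.08 with the regions of each gene summed.

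Endoderm and basement membrane genes had the smallest folds of the lists. Lamc1, a laminin chain, had 515 reads against 65 in a coding exon on chromosome 1 (153221551 to 153221726), 6.53-fold (5.04 to 8.59), and Col4a1, a basement membrane collagen, had 283 against 43 (5.43-fold, 3.93 to 7.67). Both, with Col4a2 (5.40-fold), Lama1 (5.61-fold) and the endoderm regulator Gata6 (59 against 8, 6.08-fold), were picked out after their values were seen. Of the members named by the rule, Thbd had 167 against 0 (at least 45.9-fold), Sox17 63 against 2 in an intron (26.0-fold, 6.90 to 219), Sox7 87 against 7 (10.3-fold) and Sparc 103 against 10 (8.50-fold). The 9 listed of 28 genes had a median log2 of -2.70 (6.53-fold with zeros at their bound), at the 99.9 percentile, and 5 of the 9 encode matrix proteins. Leaving out any 1 gene gave percentiles from 99.3 to 99.98, which cannot show how far the 5 matrix genes together set the median. Of the other 4, Thbd (-8.11) and Sox17 (-4.39) lay below the median of the matched random lists (-4.02). Sox7 (-3.27) and Gata6 (-2.53) lay above it.

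The other 11 lists with a percentile lay inside the central 95%, so 2 of 13 lay outside, where chance puts 5%. In the mesoderm list (12 of 33 genes, 6.88 percentile, median 17.4-fold with zeros at their bound), which lay outside at 0.67 with a pseudocount of 2, 8 genes had no double-knockout reads, among them the smooth muscle actin gene Acta2 (118 wild-type reads), Tbx20 (99), Twist1 (89) and Snai1 (45). In the pluripotency list (14 of 37, 84.4 percentile, 10.2-fold), the Nodal antagonist gene Lefty2 had 128 against 0 (log2 -7.73, but -4.76 as the mean over its 3 regions) and Nr5a2 85 against 0 in an intron. Nodal had 164 against 1 (135-fold, 23.9 to 5375) and Lefty1 20 against 0. Pou5f1 had 55 against 6 (7.56-fold, 3.26 to 21.5), while Nanog and Sox2 were not listed. By log2 value, 8 of the 14 pluripotency genes had folds more than 1.5-fold smaller than the median of all genes, and 3 had folds that much larger. In the LIF and STAT3 list (11 of 22, 89.2 percentile, 11.6-fold), the LIF receptor gene Lifr had 67 against 1 (55.3-fold, 9.58 to 2215), Lif 104 against 4 (21.4-fold), Pim1 157 against 7 (18.5-fold) and Grb2 66 against 3 in an upstream region.

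For the m6A machinery (9 of 26, 91.0 percentile, 10.7-fold), Zc3h13, a methyltransferase cofactor, had 203 against 8 (20.9-fold, 10.4 to 49.1), beside Wtap, Fto and Alkbh5 above, and the list lay outside the central 95%, at 98.3, with every region counted. In the Wnt list (15 of 48, 85.6 percentile, 13.2-fold), Myc, a target of the pathway, had 233 against 6 (32.0-fold, 14.5 to 88.2) and the receptor gene Fzd5 92 against 2 (37.9-fold), while the receptor genes Lrp5 and Fzd1 had 33 and 30 against 0. In the PI3K and mTOR list (17 of 34, 85.0 percentile, 12.8-fold), Irs1 was followed by the phosphatase gene Phlpp1 (66 against 0 in an intron), the kinase gene Akt1 (38 against 0) and Tsc1, an inhibitor of mTOR (93 against 1, 76.7-fold). The DNA methylation and imprinting list (16 of 40, 68.4 percentile, 15.3-fold) held the imprinted genes Grb10 (63 against 0), Ndn (62 against 0), Igf2 (141 against 1 in an intron, 116-fold) and Cdkn1c (125 against 1, 103-fold).

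In the Polycomb and chromatin list (19 of 37, 88.8 percentile, 9.90-fold), Cbx6 had 78, Smarca4 59, Ezh1 37 and Cbx7 35, each against 0. The regions of Smarca4 and Ezh1 lay in introns. In the fibroblast list (11 of 31, 50.015 percentile, 13.4-fold), the collagen genes Col1a1 and Col5a1 had 108 and 72 against 0, the matrix glycoprotein gene Thbs1 526 against 5 in its 3'UTR (86.8-fold, 36.9 to 268) and Vim 37 against 0. That list's percentile was 2.39 with the regions of each gene summed and 0.03 with every region counted, both outside the central 95%. In the cell cycle list (10 of 37, 91.7 percentile, 9.93-fold), Ccnd3 had 86 against 1 in an intron (70.9-fold), Mcm3 25 against 0, Plk1 24 against 0 and Mcm4 19 against 0. Of 86 ribosomal protein genes 6 were listed (80.3 percentile, 13.9-fold). For 4 of them the region used was an upstream one, including Rpl8 (58 against 2) and Rpl7 (135 against 11), while Rpl32 had 69 against 0. Of 27 housekeeping genes 3 were listed, the actin genes Actb (150 against 16, 7.73-fold) and Actg1 (46 against 1) and the chaperone gene Hsp90ab1 (35 against 1). The mitochondrial list, a pattern of gene symbols, matched no symbol of the table or of the RefSeq table and gives no value. For comparison, 3455 of 21900 protein-coding genes (15.8%) were listed. The same factor put the medians of the endoderm, m6A machinery, LIF and STAT3 and ribosomal lists above 0 (1.07, 0.34, 0.25 and 0.03) by construction, and lists are compared by percentile.

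**Figure D2:**
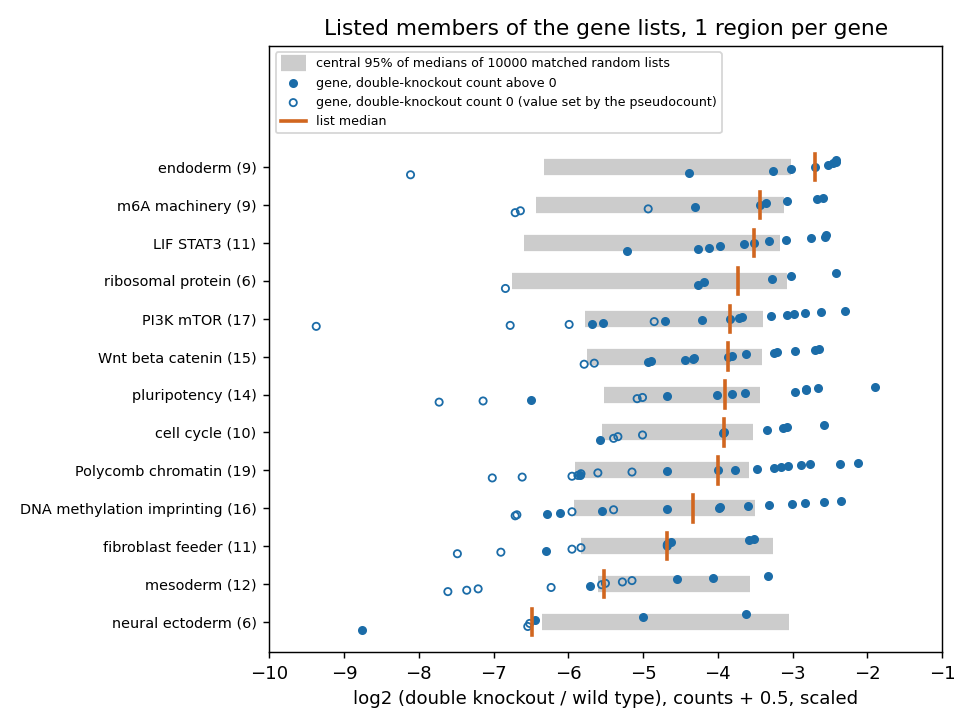
Each point is a listed gene (1 region per gene), placed by its log2 of double knockout over wild type on the x axis, with the 13 lists on the y axis and the number of listed genes in brackets. Orange bars are list medians and grey bars the central 95% of medians of 10000 matched random lists; the endoderm median (-2.70) lies to the right of its grey bar and the neural median (-6.48) to the left.

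By the authors' annotation, 3732 regions (55.7%) overlapped a coding exon or UTR, 1097 (16.4%) lay in introns only and 1358 (20.3%) had no gene. Coding sequence was overlapped by 2914 regions (43.5%), 3'UTRs by 937 (14.0%) and 5'UTRs by 404 (6.03%). Regions with no double-knockout reads made up 36.1% of exonic regions (34.6 to 37.7), 70.9% of intronic ones (68.1 to 73.6) and 71.9% of unannotated ones (69.5 to 74.3). Exonic regions with the same wild-type counts as the intronic and unannotated ones had shares of 42.4% and 42.7%. The share also followed read number, from 84.3% at 15 to 19 wild-type reads to 3.45% in the 29 regions with 1000 or more. Between the same groups the fold of the summed counts fell from 59.9 to 13.7. Counting error in the double-knockout library alone would leave that fold level. Whether the selection of regions shaped the fall was not tested.

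Genes with many regions were singled out after their values were seen, and counts summed over their listed regions describe those regions and not the whole gene. Plec, the cytoskeletal linker plectin, had 27 regions on chromosome 15 with log2 values from -4.79 to -2.58, all with double-knockout reads, and a sum of 13036 reads against 1139. The 13 regions of the scaffold gene Ahnak ran from -3.78 to -1.93 (2389 against 310) and the 18 of Lamc1 from -6.66 to -2.27 (2760 against 290, with 4 regions at 0). Flnc, an actin crosslinker of muscle, had 14 regions from -8.23 to -3.18, 9 of them without double-knockout reads, summing to 1888 against 11. The 9 regions of Nes ran from -9.16 to -5.79 (2184 against 11, with 7 at 0) and the 8 of Thbs1 from -7.96 to -5.10 (1302 against 7, with 5 at 0). Over 734 genes with several exonic regions, 52.1% of the variance of the log2 values lay between genes, against a median of 31.9% and a highest value of 36.8% in 1000 shuffles.

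**Figure D3:**
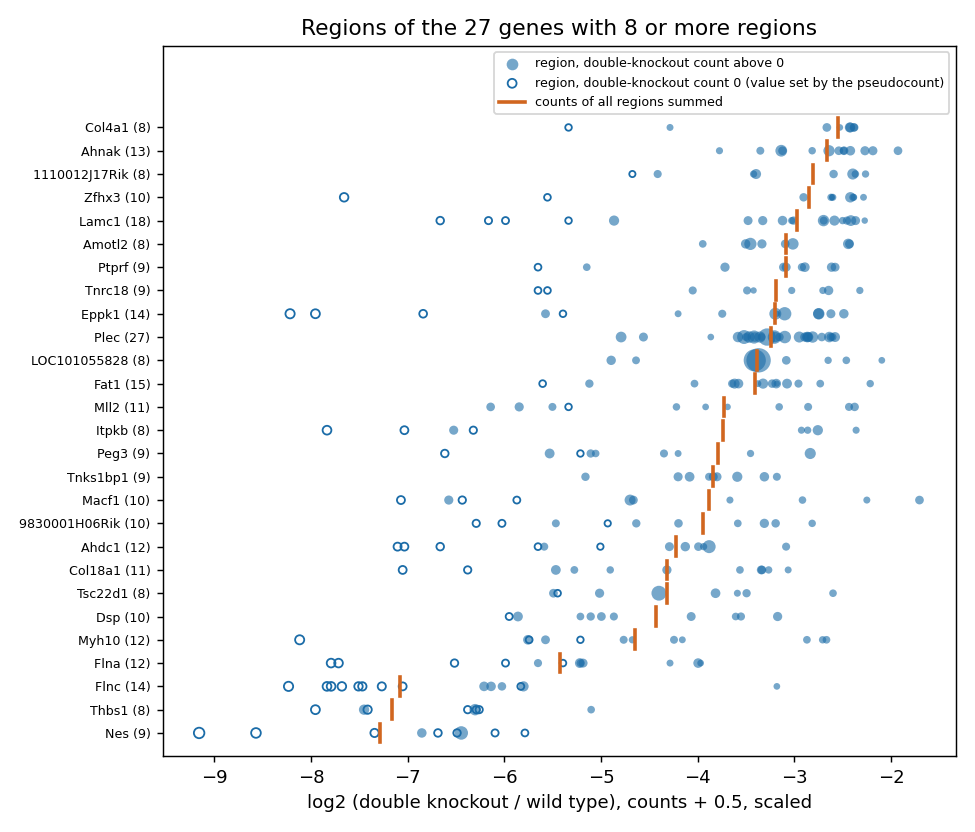
Each circle is a region of 1 of the 27 genes with 8 or more regions, placed by its log2 of double knockout over wild type on the x axis and its gene on the y axis (number of regions in brackets, circle area growing with the wild-type count, open circles for a double-knockout count of 0). Orange bars are the values of the counts summed over the listed regions, from -7.29 for Nes to -2.55 for Col4a1.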

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

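The exonic subset, the lists with summed, exonic or no upstream regions, and all settings of the within-gene agreement were chosen after seeing the data; the others were planned. The median log2 value (-4.93) was -5.21 without the authors' constant, -1.17 with a median-ratio factor, -5.74 with the pseudocount halved and -3.42 with it 4 times as large. It was -4.44 in regions at or above the median mean count, -4.85 with 1 region per gene, -4.55 in the denser part of the regions and -4.27 in exonic regions. The pseudocount and the factor enter the value directly, and for the subsets the cause was not tested. The number of regions at least 2-fold lower (6697) was 983 with the median-ratio factor, and 3383 above the median mean count and 3882 with 1 region per gene, where fewer regions were counted. The neural list's percentile (1.52) was 7.07 and 4.54 with the smaller and larger pseudocount, and that of the mesoderm list (6.88) was 0.67 with the larger one. Counting every region took the m6A machinery from 91.0 to 98.3 and the fibroblast list from 50.015 to 0.03, and summing the regions of a gene took the latter to 2.39; the cause was not tested, and counting every region treats regions of a gene as independent. The remaining 135 of 141 list alternatives kept their place inside or outside the central 95%. Those of scaling could not change it, since they shift every gene alike. Moves inside it were not counted, such as the imprinting list from 68.4 to 11.8 with every region counted. Of 316 alternatives of named genes, 310 stayed within counting error. Part of this was fixed in advance: for a double-knockout count of 0 that error had no lower end, and for genes with 1 region the mean over regions changed nothing. The other 6 moved with the mean over a gene's regions, to -6.57 for Tiam1, -6.37 for Irs1, -6.90 for Sox11, -4.76 for Lefty2, -3.12 for Dst and -2.93 for Fam129b. These 316 leave out the median-ratio factor, which shifted every gene alike and put 16 of 79 above 0. The within-gene share lay above its shuffles in each setting tried (49.9% to 57.4%). No paired analysis was possible because each group had 1 library. Equal library totals, input abundance and overlap of peak lists were not run, since the table gives none of them, and exonic ribosomal regions were too few. Regions of one gene share a direction because all listed regions do, so that agreement carries no information. A region with 15 wild-type reads and 0 in the double knockout allows a bound of only 4.12-fold, so depth limits the folds of such regions.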

Other observations

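The tests of within-gene agreement, exonic regions, summed regions, matched shares and dense regions in this part, and what each explanation predicts, were set after the results were seen, while the list percentiles with their pseudocounts and the mean over regions were planned. Among genes not yet described, the actin crosslinker gene Flna had 12 regions with log2 values from -7.79 to -3.97 (1224 reads against 23 in sum, 5 regions at 0) and the non-muscle myosin gene Myh10 12 from -8.12 to -2.67 (1017 against 33). The desmosomal gene Dsp had 10 regions from -5.95 to -3.17 (1167 against 44), and Peg3, an imprinted gene, 9 from -6.62 to -2.84 (1116 against 66). The protocadherin gene Fat1 had 15 from -5.60 to -2.22 (1949 against 151). The matricellular genes Cyr61 (947 against 31, 25.2-fold) and Ctgf (600 against 19, 26.0-fold) had log2 values of -4.63 and -4.67, near the median of all genes (-4.85). The densest region, in an intron of Fam19a1 on chromosome 6 (96592979 to 96593202), had 6724 reads against 398 (13.9-fold, 12.6 to 15.5).

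The first pattern was that folds differed between genes. One factor common to all regions, such as depth or immunoprecipitation yield, would leave the between-gene share of variance among its shuffles, and the observed 52.1% lay above the highest of them, 36.8%. It may still account for part of every fold. Selection by the authors cannot be excluded as the origin of the shared direction, since 0 listed regions had at least as many double-knockout as wild-type reads. Nor can it be excluded as a source of the larger summed fold at low wild-type counts (59.9 at 15 to 19 reads, 13.7 at 1000 or more).

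The second pattern was the larger folds of the neural list and the smaller folds of the endoderm and basement membrane list. For endoderm, different read depth and annotation were argued against by percentiles of 99.89 among count-matched lists and 99.92 among exonic regions. A shortage of differentiated cells of every germ layer cannot be told apart: the endoderm list was at 99.66 at the larger pseudocount, but 5 of its 9 genes are matrix genes that other cells express, Thbd and Sox17 had folds of at least 45.9 and of 26.0, and mesoderm ran from 0.67 to 24.6 over the settings (6.88 in the main one). For neural genes, percentiles of 1.52 among count-matched lists, 0.495 in exonic regions, 0.575 with the mean over regions and 0.08 with regions summed go against depth, but 7.07 and 4.54 at other pseudocounts lie inside the central 95%, so with 6 genes the difference cannot be told apart from an effect of depth on zero counts. Whether transcript abundance or methylation differed cannot be told apart, as the table had 0 input columns.

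The third pattern was that intronic and unannotated regions more often lacked double-knockout reads. Lower wild-type counts were argued against, since at the same counts the share exceeded that of exonic regions by 28.5 percentage points for intronic and 29.3 for unannotated regions. Stacks of reads at a few positions in the wild-type library alone would place the densest regions outside exons more often. Of the 67 densest regions, 71.6% were intronic or unannotated, against 36.7% of all. Only 4 of these 67 had no double-knockout reads, however, so most of the densest regions were not stacks of the wild-type library alone. The intronic region of Tiam1 was among the 4, and for it such a stack cannot be excluded. The difference was also 27.8 and 28.4 points in regions below the median density, against 30.4 and 31.0 above it. Stacks among the densest regions are thus not its only source. A part for them above the median, and small stacks, cannot be excluded without read positions. No biological explanation was tested for this pattern.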
